A study of Homo sapiens with 12 samples.

How the data were processed

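The deposited data were read counts per gene for 12 RNA-seq libraries from 2 human breast cancer cell lines, MCF-7 and MDA-MB-231. Per the labels, cells of each line were treated for 24 h with 1 µM GDC-0941 or with DMSO, total RNA was extracted on silica columns, and libraries were made with the TruSeq RNA kit, which does not mark the strand of the RNA. GDC-0941 (pictilisib) inhibits class I PI3K enzymes, and DMSO is its solvent. Each of the 4 groups held 3 libraries, numbered by the submitters. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

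The authors deposited 1 file of raw counts per library, covering 65988 Ensembl genes, with no row outside the genes. Per the submitters' processing notes, the tools were TopHat2 2.1.0, HTSeq and DESeq2 and the build was GRCh38; the notes give no role for each tool, and the annotation release and strand setting are not given in the sources used here. Without strand, reads from overlapping genes on opposite strands cannot be told apart, and named genes with such a neighbour are marked as uncertain. Genes with close copies, among them ribosomal protein genes with processed pseudogenes, histones and HLA genes, are uncertain as well, since reads may be shared between copies. Gene names, types and coordinates came from GENCODE release 29 on GRCh38, matched by Ensembl identifier: 56927 identifiers had a name, and these held 99.87% of all counts. Library totals ran from 22655898 to 35493081 counts. With 3 counts as the floor, a gene at 0 in a library lay below 0.0845 to 0.132 CPM, the count scaled to the library total. PCR reads carry no molecular identifiers, so floors and counting intervals cover counting error only.

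The counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr with the 4 groups, leaving 18028. Libraries were scaled by TMM, and a robust quasi-likelihood model with a term per group was fitted to all 12 libraries, so that both lines shared 1 estimate of the spread. The common biological coefficient of variation was 0.0472. Contrasts tested were 4: GDC-0941 against DMSO in each line, the difference between these responses (MDA-MB-231 minus MCF-7), and DMSO-treated MDA-MB-231 against DMSO-treated MCF-7. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes were computed from the F statistic, and levels are given as TMM-scaled CPM. The overlap of calls between lines was set against the number expected of independent lists and tested with a two-sided Fisher's exact test. That test takes genes as independent replicates, which they are not. The treatment contrasts share no library but share the estimate of the spread.

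The gene lists, the rule for named genes and the first group of other settings below were fixed before the data were examined. The 30 lists cover PI3K signalling and FOXO targets, lipid, glucose and amino acid metabolism, cell cycle, ribosomes, stress, immune and lineage programmes, and markers of other cell types. Each was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 30 lists of a contrast, and again with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, was run beside it. Of the genes on these lists and on 3 lists chosen after seeing the data, 6 had no match in the files.

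The rule for named genes takes, per treatment contrast, the 6 largest rises and 6 largest falls among protein-coding genes with at least 5 CPM in a compared group and CPM that do not overlap between groups, up to 4 members of each list with the lowest p, and a set of anchor genes whatever their result. For the difference between lines and for the baseline it takes 5 each way, for the difference without the requirement of non-overlap, and for the baseline with line identity genes. Any other gene is said to have been chosen after its values were seen.

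Other settings fixed in this way were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, other count filters, fits of part of the libraries, tests against a minimum fold change, the replicate number as a block, and each library left out in turn. Offsets for transcript length and GC content, removal of mitochondrial genes, scaling by library size alone and counts of calls at 1 CPM or more were chosen after seeing the data. The procedure was tested on simulated counts for MCF-7 GDC-0941 against DMSO with 17735 genes, of which 50 were changed at each fold change. Of changed genes at 1 CPM or more it recovered 66.7% at a 1.25-fold change, 81.4% at 1.5-fold, 90.6% at 2-fold and 100% at 4-fold. Of all changed genes it recovered 56%, 70%, 60% and 90%, with 8 false calls. Far fewer genes were changed here than were called in the MCF-7 data. The simulation therefore does not test scaling or false calls where most genes move. No gene, library or file was left out other than by the count filter.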

Results

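RNA-seq libraries were made from 2 breast cancer cell lines to find how inhibition of PI3K signalling changes gene expression. MCF-7 is a luminal, estrogen receptor positive line, and MDA-MB-231 is an estrogen receptor negative line with mesenchymal features. Each line was treated for 24 h with 1 µM GDC-0941 or DMSO, with 3 libraries in each of 4 groups. The MCF-7 DMSO libraries held 32439639, 22655898 and 35493081 counts and the MCF-7 GDC-0941 libraries 28685184, 28864529 and 27474512. The MDA-MB-231 DMSO libraries held 28124183, 29973278 and 27985199 and the MDA-MB-231 GDC-0941 libraries 27133143, 31600976 and 34675540. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom between 2.52 and 10.9 for pairs within a group. The first principal component separated the lines and carried 89.6% of the variance, and the next carried 5.77%. Unless stated otherwise, values below are log2 fold changes of GDC-0941 against DMSO ± standard error with 3 libraries per group, levels are mean CPM ± SD (n = 3), and adjusted p-values are from edgeR's quasi-likelihood test for genes and camera for lists.

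The first comparison asked which genes respond to GDC-0941 in MCF-7. Genes of DNA replication, mitosis and ribosome biogenesis fell, and genes known to be activated by FOXO transcription factors, which AKT restrains, rose. RRM2, a subunit of ribonucleotide reductase, fell from 349 ± 5.52 to 53.3 ± 1.6 CPM (-2.71 ± 0.04, adjusted p = 6.24e-35). KLHL24, a FOXO target, rose from 11.6 ± 1.47 to 142 ± 3.57 CPM (3.64 ± 0.07, adjusted p = 1.18e-31), and IRS2, an adaptor of the insulin receptor, rose from 19.5 ± 1.11 to 118 ± 8.08 CPM (2.61 ± 0.06). Lipid synthesis genes and endoplasmic reticulum chaperones fell, and lysosome, interferon and CDK inhibitor genes rose. Of 18028 genes tested, 5885 were higher and 5695 lower, together 64.2%, and 2316 and 1392 of these changed at least 2-fold. Of the calls 50.8% were higher, against 59.3% with upper quartile scaling and 57.1% with library size scaling. The CPM of the groups did not overlap for 11198 of the 11580 called genes and for 68.1% of all genes, where chance gives 10%.

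The largest rises by the fixed rule were N4BP2L1 (5.05 ± 0.21), SEMA6C (4.89 ± 0.11), YPEL1 (4.82 ± 0.24), ADHFE1 (4.30 ± 0.31), CALCOCO1 (4.27 ± 0.06) and FAXDC2 (4.11 ± 0.16). SEMA6C, a transmembrane semaphorin, went from 1.82 ± 0.216 to 54.9 ± 1.58 CPM, and CALCOCO1 from 9.62 ± 0.143 to 185 ± 0.951 CPM. The largest falls were P2RY6 (-3.99 ± 0.32), MCM10 (-3.81 ± 0.07), AJAP1 (-3.66 ± 0.30), DPF1 (-3.50 ± 0.19), FAM111B (-3.44 ± 0.07) and CHAC2 (-3.03 ± 0.12). MCM10, which helps to start replication, fell from 77.7 ± 1.04 to 5.54 ± 0.393 CPM. The highest adjusted p among these 12 genes was that of AJAP1, 1.49e-12. On GRCh38 with GENCODE 29, N4BP2L1 lies on chromosome 13, 32400723 to 32428311, SEMA6C on chromosome 1, 151131685 to 151146664, YPEL1 on chromosome 22, 21697544 to 21735834, ADHFE1 on chromosome 8, 66432486 to 66468907, CALCOCO1 on chromosome 12, 53708517 to 53727745 and FAXDC2 on chromosome 5, 154818491 to 154859252. P2RY6 lies on chromosome 11, 73264505 to 73298617, MCM10 on chromosome 10, 13161554 to 13211104, AJAP1 on chromosome 1, 4654732 to 4792534, DPF1 on chromosome 19, 38211006 to 38229714, FAM111B on chromosome 11, 59107185 to 59127410 and CHAC2 on chromosome 2, 53767792 to 53775196. YPEL1, FAXDC2 and CHAC2 overlap a gene on the opposite strand, so their counts are uncertain.

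Of 38 FOXO target genes, 32 rose and 1 fell, with a median of 1.47 (adjusted p = 4.82e-28; median 1.496 with genes at 0 counts set to their bound). Among them were YPEL3 (3.42 ± 0.05), CCNG2 (2.79 ± 0.06), TXNIP, an inhibitor of glucose uptake (2.04 ± 0.04), and PIK3IP1, a negative regulator of PI3K (3.90 ± 0.12). Of 23 receptor tyrosine kinases and adaptors, 15 rose and 6 fell (median 0.62, adjusted p = 0.000202; adjusted p = 0.0846 with an estimated correlation). ERBB3 rose by 1.63 ± 0.04, INSR by 1.496 ± 0.06, IRS1 by 1.10 ± 0.04 and IGF1R by 0.98 ± 0.05. Of 33 PI3K, AKT and mTOR pathway components, 14 were higher and 13 lower, and the list did not pass (adjusted p = 0.42). DEPTOR, an mTOR inhibitor, rose by 2.23 ± 0.10 and AKT1 changed by -0.74 ± 0.03, while PIK3CA rose by 0.30 ± 0.06 and PTEN by 0.51 ± 0.04.

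All but 2 of the 40 G1/S and replication genes fell, with 1 higher and 1 not called (median -1.90, adjusted p = 1.18e-47). UHRF1 changed by -2.75 ± 0.04, CDC6, which loads the replicative helicase, by -2.82 ± 0.06, and CCND1 (cyclin D1) by -0.43 ± 0.03. Of 36 G2/M and mitosis genes, 35 fell and 1 rose (median -1.03, adjusted p = 5.17e-25). MKI67 was at -1.80 ± 0.10, FOXM1 at -1.43 ± 0.05, PLK1 at -1.14 ± 0.04, CDC20 at -1.21 ± 0.04 and BIRC5 at -1.33 ± 0.04; FOXM1 overlaps genes on the opposite strand. Of 25 CDK inhibitors and p53 targets, 20 rose and 3 fell (median 0.52, adjusted p = 1.41e-05), among them CDKN1B (p27) by 0.66 ± 0.04 and TP53INP1, which lies within a gene on the opposite strand, by 1.85 ± 0.06. Of 20 apoptosis regulators, 12 were higher and 4 lower, and the list did not pass (adjusted p = 0.172), although BBC3 (PUMA) rose by 2.62 ± 0.07 and BMF by 2.87 ± 0.09.

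Of 36 ribosome biogenesis genes and MYC targets, 32 fell and 2 rose (median -1.06, adjusted p = 5.94e-22). NOLC1 and DDX21, nucleolar proteins, changed by -1.61 ± 0.04 and -1.45 ± 0.04, and the polyamine enzymes SRM and ODC1 by -1.67 ± 0.05 and -1.35 ± 0.04. The 2 that rose were MYC itself (0.93 ± 0.04) and NPM1 (0.15 ± 0.03). Of 76 cytosolic ribosomal protein genes, 65 rose and 3 fell (median 0.41, adjusted p = 8.31e-09; adjusted p = 0.382 with an estimated correlation). RPL12 was at 0.68 ± 0.03 and RPS26 at -0.79 ± 0.06. Their share of all counts went from 4.13 ± 0.0740% to 5.84 ± 0.117% (SD, n = 3). All 13 mitochondrially encoded mRNAs rose (median 1.62, adjusted p = 1.9e-17; adjusted p = 0.0558 with an estimated correlation), MT-CO1 the most by 2.13 ± 0.04. The share of counts from the mitochondrial chromosome went from 0.785 ± 0.0300% to 2.90 ± 0.0413% (SD, n = 3). At the same time 25 of 33 nuclear genes of oxidative phosphorylation fell and none rose (median -0.45, adjusted p = 1.37e-05; adjusted p = 0.288 with an estimated correlation). CYCS, cytochrome c, was at -2.02 ± 0.04.

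**Figure D1:**
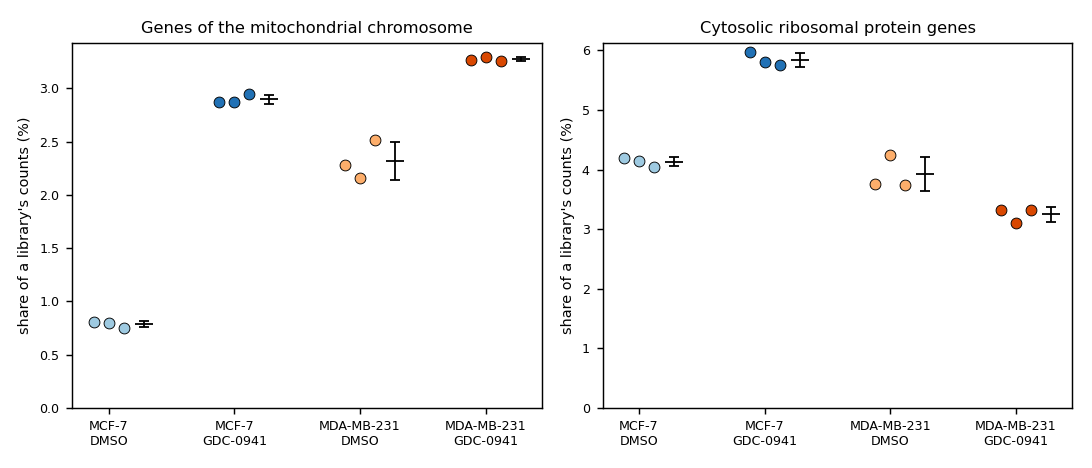
Share of each library's counts, in percent, from genes of the mitochondrial chromosome (left) and from cytosolic ribosomal protein genes (right), for the 4 groups. Points are libraries and bars are the mean ± SD of 3; the mitochondrial share was higher after GDC-0941 in both lines, and the ribosomal protein share was higher in MCF-7 and lower in MDA-MB-231.

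Of 17 fatty acid synthesis genes, 14 fell and 1 rose (median -0.62, adjusted p = 1.86e-06). FASN was at -1.05 ± 0.03, SCD at -0.99 ± 0.04 and SREBF1 at -0.61 ± 0.04. Of 26 cholesterol biosynthesis genes, 20 fell and 3 rose (median -0.45, adjusted p = 0.00032), including DHCR24 by -1.13 ± 0.04 and LDLR by -0.28 ± 0.04. HMGCR, the rate-limiting enzyme, changed by -0.13 ± 0.05 (adjusted p = 0.0126), a call lost with upper quartile scaling (-0.01, adjusted p = 0.819), library size scaling (0.438), without mitochondrial genes (0.0525), and without MCF-7 DMSO replicate 3 (0.158), GDC-0941 replicate 1 (0.11) or GDC-0941 replicate 2 (0.176). HMGCR, SREBF1 and LDLR overlap genes on the opposite strand. Of 22 glycolysis genes, 14 fell and 3 rose (median -0.42, adjusted p = 1.21e-07; adjusted p = 0.0518 with an estimated correlation). LDHA was at -1.80 ± 0.03, PKM at -1.39 ± 0.03 and HK2 at -0.66 ± 0.04. Of 33 ATF4 targets, 18 fell and 8 rose (median -0.29, adjusted p = 0.0344; adjusted p = 0.0803 with an estimated correlation, 0.0636 with upper quartile scaling and 0.0552 with library size scaling). The amino acid transporter SLC7A5 changed by -1.74 ± 0.03, SLC7A11 by -0.97 ± 0.06 and ASNS by -0.64 ± 0.05. Of 19 endoplasmic reticulum chaperone genes, 14 fell and 4 rose (median -0.73, adjusted p = 4.32e-06). HSPA5 (BiP) was at -1.02 ± 0.03. Of 40 lysosome and autophagy genes, 26 rose and 5 fell (median 0.55, adjusted p = 2.42e-07). GABARAPL1 changed by 3.23 ± 0.12, CTSF by 2.78 ± 0.09, ULK1 by 0.93 ± 0.04, SQSTM1, which overlaps a gene on the opposite strand, by 0.69 ± 0.04, and CTSD by -0.63 ± 0.03.

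Of 36 interferon response genes, 27 rose and 4 fell (median 1.00, adjusted p = 0.000121; median 0.98 with genes at 0 counts set to their bound). STAT2 was at 1.27 ± 0.06 and PARP14 at 1.35 ± 0.07 among those that rose and OAS3 at -0.92 ± 0.06 among those that fell. Of 18 NF-kappaB targets, 8 rose and 1 fell (median 0.70, 0.76 with bounds, adjusted p = 0.0197; adjusted p = 0.131 with an estimated correlation), including TNFAIP3 by 2.62 ± 0.11 and NFKBIA by 0.93 ± 0.05. All 19 immediate stress genes were called, 15 higher and 4 lower (median 0.87, adjusted p = 0.00716; adjusted p = 0.117 with an estimated correlation). FOS was at 2.76 ± 0.17 and KLF6 at 1.43 ± 0.04 among those that rose, while HSPH1, a heat shock protein, was among those that fell. Of 24 replication-dependent histone genes, 12 rose and 5 fell (median 0.32, and 0.82 for the 18 at 1 CPM or more; adjusted p = 0.0125; adjusted p = 0.0846 with an estimated correlation), including H2BC21 by 1.49 ± 0.06 and H2AC6 by 1.46 ± 0.07. Luminal markers rose in 16 and fell in 5 of 24 cases (median 0.21, adjusted p = 0.0326; adjusted p = 0.261 with an estimated correlation). GATA3 was at 0.44 ± 0.04, CLDN3 at 0.73 ± 0.05 and KRT18, which overlaps KRT8, at -0.17 ± 0.04, the last call lost with upper quartile scaling (-0.05, adjusted p = 0.199). Of 26 basal and mesenchymal markers, 13 rose and 3 fell, with a median of 0.65, or 0.52 with bounds and 1.05 for the 15 at 1 CPM or more. CAV1 was at 2.70 ± 0.06 and CD44 at 1.78 ± 0.04. That list's adjusted p of 0.029 was lost with an estimated correlation (adjusted p = 0.0713), upper quartile scaling (0.0506), length and GC offsets (0.0542), without MCF-7 DMSO replicate 3 (0.066) and without MDA-MB-231 DMSO replicate 2 (0.0692). Of 23 YAP-TEAD targets, 15 rose and 3 fell (median 0.40, 0.46 with bounds, adjusted p = 0.0147; adjusted p = 0.233 with an estimated correlation). CCN2 was at 1.505 ± 0.14.

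Lists that did not pass in MCF-7 were estrogen receptor targets (13 higher, 14 lower of 32, adjusted p = 0.261), ERK pathway output (13 higher, 7 lower of 27, adjusted p = 0.0731), hypoxia response (8 higher, 6 lower of 20, adjusted p = 0.466) and antigen presentation (2 higher of 10, adjusted p = 0.405). Immune markers (1 higher, 2 lower of 5, adjusted p = 0.353) and markers of fibroblast, endothelial, adipocyte and erythroid cells (4 higher, 3 lower of 10, adjusted p = 0.871) did not pass either. For the hypoxia, immune and fibroblast lists the median, mean and test differed in sign. Of the estrogen receptor targets, PGR rose by 0.60 ± 0.06 and GREB1 by 0.68 ± 0.04, and ESR1 itself was at 0.08 ± 0.07 (adjusted p = 0.325), which passed with upper quartile (0.0178) and library size scaling (0.0393) and in a fit of the 6 MCF-7 libraries (0.00421). Of the ERK targets, SPRY4 was at -1.30 ± 0.14, DUSP6 at 0.61 ± 0.14 and DUSP4 at -0.08 ± 0.04 (adjusted p = 0.095; 0.000833 with length and GC offsets, 0.0493 without MCF-7 GDC-0941 replicate 2 and 0.0371 without MDA-MB-231 DMSO replicate 2). In all, 22 of 30 lists passed, and 10 with an estimated correlation. Adjusted over the list alone, the counts differed from those over all genes for FOXO targets (33 higher), lysosome genes (27 higher), estrogen receptor targets (14 higher), interferon genes (28 higher) and histones (6 lower).

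**Figure D2:**
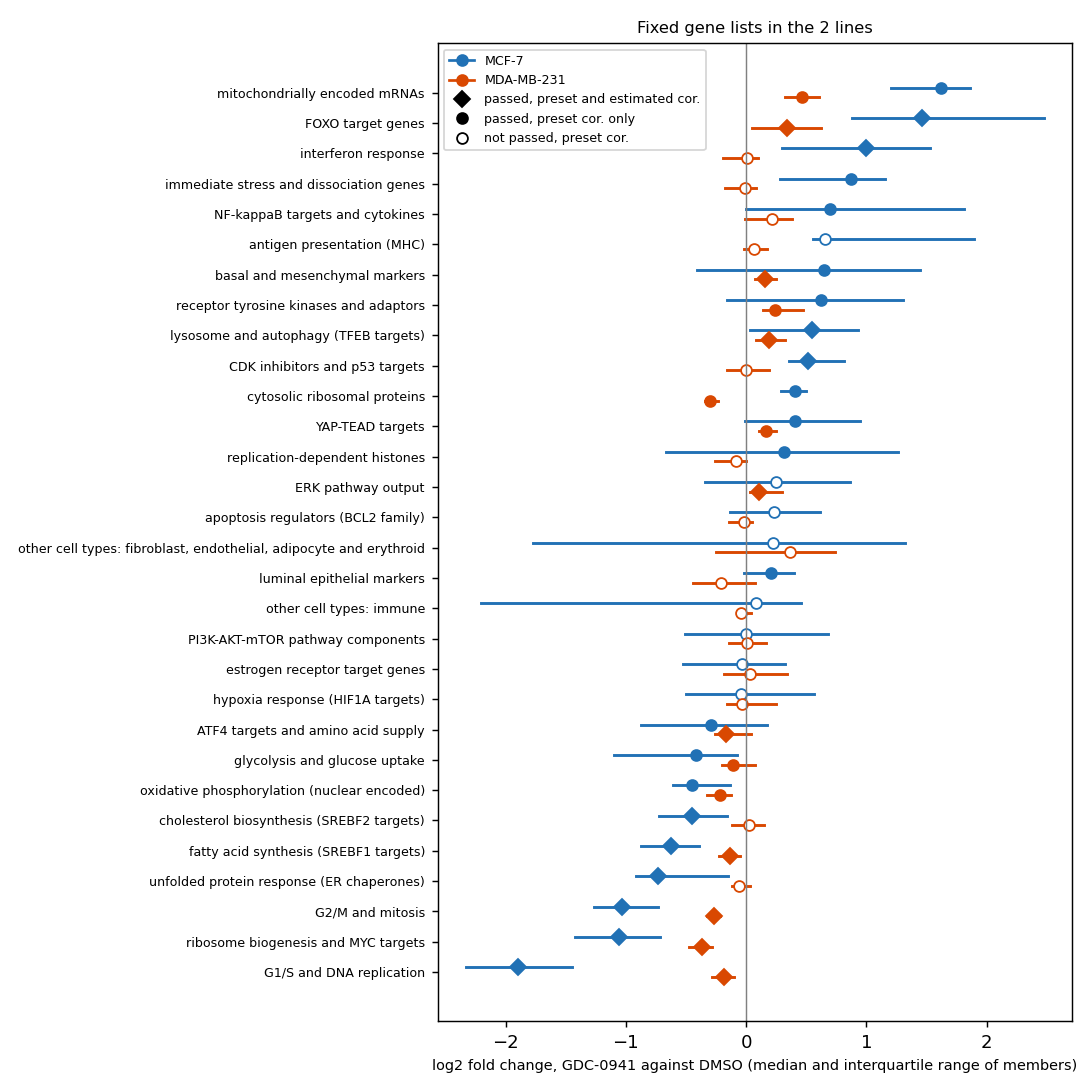
Median log2 fold change of each of the 30 fixed lists, GDC-0941 against DMSO, in MCF-7 (blue) and MDA-MB-231 (orange), with the interquartile range of its members. Diamonds passed camera with both correlations, filled circles with the preset correlation only and open circles not at all; the G1/S and replication list lay at -1.90 in MCF-7 and -0.18 in MDA-MB-231.

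The second comparison asked which genes respond in MDA-MB-231. Genes of ribosome biogenesis, mitosis and replication fell and FOXO target and lysosome genes rose, by smaller amounts than in MCF-7 for each of these lists. ODC1 fell from 419.9 ± 18.8 to 262 ± 5.32 CPM (-0.68 ± 0.04, adjusted p = 6.95e-16) and KLHL24 rose from 11.4 ± 0.927 to 24.4 ± 1.06 CPM (1.10 ± 0.08, adjusted p = 1.77e-13). Basal and mesenchymal markers and targets of ERK signalling rose, and ribosomal protein genes fell at the preset correlation (adjusted p = 0.143 with an estimated correlation). Of 18028 genes, 2916 were higher and 2761 lower, together 31.5%, with at least 2-fold changes in 262 and 40. Of the calls 51.4% were higher, against 44.8% with RLE scaling, 44.3% with DESeq2, 49.5% with length and GC offsets and 43.0% without mitochondrial genes, and 55.65% with upper quartile and 56.5% with library size scaling. The CPM of the groups did not overlap for 5321 of the 5677 called genes and for 41.2% of all genes, where chance gives 10%.

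The largest rises by the fixed rule were TCP11L2 (1.55 ± 0.17), BAIAP3 (1.33 ± 0.09), PLA2G6, a phospholipase (1.27 ± 0.14), SNED1 (1.24 ± 0.12), ITGA10, an integrin subunit (1.24 ± 0.18), and AHNAK2 (1.22 ± 0.08). AHNAK2 went from 70.1 ± 9.64 to 163 ± 4.52 CPM. The largest falls were RIMS2 (-0.93 ± 0.18), ARRDC4 (-0.88 ± 0.10), ARTN, a neurotrophic factor (-0.85 ± 0.14), GAL, the galanin precursor (-0.82 ± 0.13), CRABP2, a retinoic acid binding protein (-0.76 ± 0.09), and SOCS2, a regulator of cytokine signalling (-0.76 ± 0.06). The highest adjusted p among these 12 genes was that of RIMS2, 7.3e-05. On GRCh38 with GENCODE 29, TCP11L2 lies on chromosome 12, 106301929 to 106347015, BAIAP3 on chromosome 16, 1333601 to 1349441, PLA2G6 on chromosome 22, 38111495 to 38205690, SNED1 on chromosome 2, 240998838 to 241095568, ITGA10 on chromosome 1, 145891208 to 145910189 and AHNAK2 on chromosome 14, 104937244 to 104978357. RIMS2 lies on chromosome 8, 103500748 to 104256094, ARRDC4 on chromosome 15, 97960698 to 97973838, ARTN on chromosome 1, 43933320 to 43937241, GAL on chromosome 11, 68683779 to 68691175, CRABP2 on chromosome 1, 156699606 to 156705816 and SOCS2 on chromosome 12, 93569814 to 93583487. TCP11L2, BAIAP3, PLA2G6, SNED1 and SOCS2 overlap genes on the opposite strand, so their counts are uncertain.

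Of 38 FOXO target genes, 25 rose and 4 fell (median 0.34, adjusted p = 2.73e-11). YPEL3 was at 1.04 ± 0.07, CCNG2 at 0.78 ± 0.06 and PIK3IP1 at 0.94 ± 0.19, while TXNIP fell from 322 ± 2.41 to 218 ± 3.14 CPM (-0.56 ± 0.03). Of 23 receptor tyrosine kinases and adaptors, 14 rose and none fell (median 0.24, adjusted p = 1.29e-05; adjusted p = 0.065 with an estimated correlation). INSR was at 0.63 ± 0.06, IGF1R at 0.58 ± 0.06, IRS2 at 0.48 ± 0.05 and IRS1 at 0.15 ± 0.04, the last lost with length and GC offsets (-0.01, adjusted p = 0.859). ERBB3 was at 0.30 ± 0.10 (adjusted p = 0.0211), which was lost with limma-voom (0.168), no count filter (0.0742), length and GC offsets (0.127), a fit of the 6 MDA-MB-231 libraries (0.18), and without MDA-MB-231 DMSO replicate 3 (0.256), GDC-0941 replicate 1 (0.0501) or GDC-0941 replicate 2 (0.119). Of 33 PI3K, AKT and mTOR components, 8 were higher and 10 lower (adjusted p = 0.989). AKT1 was at 0.01 ± 0.04 (adjusted p = 0.919; -0.22 with length and GC offsets, adjusted p = 1.3e-07) and DEPTOR at -0.05 ± 0.24 (adjusted p = 0.929). PTEN was at -0.14 ± 0.04 (adjusted p = 0.00942; 0.0861 without MDA-MB-231 GDC-0941 replicate 1). PIK3CA was at 0.16 ± 0.06 (adjusted p = 0.0453), a call lost with RLE scaling (0.0905), DESeq2 (0.0939), no count filter (0.162), length and GC offsets (0.142), without mitochondrial genes (0.112) and in a fit of the 6 MDA-MB-231 libraries (0.0733). It was also lost without MCF-7 DMSO replicate 1 (0.0597), 2 (0.0508) or 3 (0.085), MCF-7 GDC-0941 replicate 1 (0.131) or 2 (0.112), MDA-MB-231 DMSO replicate 1 (0.134) or 2 (0.116), and MDA-MB-231 GDC-0941 replicate 2 (0.207) or 3 (0.1).

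Of 36 ribosome biogenesis genes and MYC targets, 31 fell and 1, MYC, rose by 0.30 ± 0.04 (median -0.37, adjusted p = 1.22e-28). SRM was at -0.53 ± 0.05, NPM1 at -0.50 ± 0.03, DDX21 at -0.46 ± 0.04 and NOLC1 at -0.31 ± 0.03. Of 36 mitosis genes, 32 fell and 1 rose (median -0.27, adjusted p = 1.68e-21). CDC20 was at -0.64 ± 0.04, PLK1 at -0.43 ± 0.04, BIRC5 at -0.30 ± 0.04 and FOXM1 at -0.18 ± 0.04. MKI67 was at 0.01 ± 0.10 (adjusted p = 0.958), but at -0.18 with length and GC offsets (adjusted p = 0.000559) and at -0.11 without MDA-MB-231 DMSO replicate 2 (adjusted p = 0.0183). Of 40 G1/S and replication genes, 28 fell and 1, CCND1, was higher (median -0.18, adjusted p = 2.55e-11). RRM2 was at -0.45 ± 0.04, MCM10 at -0.28 ± 0.05, CDC6 at -0.26 ± 0.04 and UHRF1 at -0.16 ± 0.04. CCND1 was at 0.10 ± 0.03 (adjusted p = 0.0138), a call lost with RLE scaling (0.0653), no count filter (0.205), without mitochondrial genes (0.0905), in a fit of the 6 MDA-MB-231 libraries (0.0898), and without MCF-7 DMSO replicate 3 (0.0718), MCF-7 GDC-0941 replicate 1 (0.131) or 2 (0.109), MDA-MB-231 DMSO replicate 2 (0.0701) or MDA-MB-231 GDC-0941 replicate 1 (0.0542). Of 25 CDK inhibitors and p53 targets, 5 were higher and 6 lower (adjusted p = 0.788). CDKN1B was at -0.04 ± 0.05 (adjusted p = 0.554) and TP53INP1 at 0.52 ± 0.10; of 20 apoptosis regulators, 2 were higher and 4 lower (adjusted p = 0.682). BMF was at 1.07 ± 0.13.

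Of 76 ribosomal protein genes, 71 fell and none rose (median -0.30, adjusted p = 2.86e-33; adjusted p = 0.143 with an estimated correlation). RPL12 was at -0.15 ± 0.03 and RPS26 at -0.41 ± 0.06; their share of counts went from 3.92 ± 0.285% to 3.25 ± 0.129% (SD, n = 3). All 13 mitochondrially encoded mRNAs rose (median 0.47, adjusted p = 1.2e-15; adjusted p = 0.0757 with an estimated correlation). MT-CO1 was at 0.68 ± 0.04 and MT-ND3 at 0.22 ± 0.04, and the mitochondrial share went from 2.32 ± 0.179% to 3.28 ± 0.0183% (SD, n = 3). Nuclear genes of oxidative phosphorylation fell in 23 and rose in 0 of 33 cases (median -0.22, adjusted p = 1.68e-11; adjusted p = 0.155 with an estimated correlation). CYCS was at -0.61 ± 0.04. Of 17 fatty acid synthesis genes, 10 fell and 1 rose (median -0.13, adjusted p = 0.000403). SREBF1 was at -0.41 ± 0.04, SCD at -0.34 ± 0.04 and FASN at -0.06 ± 0.03 (adjusted p = 0.182; 2.97e-15 with length and GC offsets, at -0.32, 0.0406 without mitochondrial genes, and 0.0348 and 0.046 without MCF-7 GDC-0941 replicate 2 and MDA-MB-231 DMSO replicate 2). Cholesterol genes did not pass (6 higher, 6 lower of 26, adjusted p = 0.967). LDLR was at 0.18 ± 0.04 and HMGCR at -0.08 ± 0.05 (adjusted p = 0.198). Of 22 glycolysis genes, 11 fell and 4 rose (median -0.11, adjusted p = 0.0086; adjusted p = 0.326 with an estimated correlation). LDHA was at -0.35 ± 0.03 and HK2 at -0.21 ± 0.04. Of 33 ATF4 targets, 16 fell and 4 rose (median -0.16, adjusted p = 0.000557). PSAT1, a serine synthesis enzyme, was at -0.54 ± 0.05, SLC7A5 at -0.22 ± 0.03 and SLC7A11 at 0.50 ± 0.05. ASNS was at -0.14 ± 0.06 (adjusted p = 0.0853), and passed with RLE scaling (0.0399), DESeq2 (0.0312), without mitochondrial genes (0.0326), and without MCF-7 GDC-0941 replicate 1 (0.03) or 2 (0.0346).

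Of 40 lysosome and autophagy genes, 24 rose and none fell (median 0.19, adjusted p = 1.05e-09). ULK1 was at 0.59 ± 0.05, GABARAPL1 at 0.54 ± 0.09, SQSTM1 at 0.48 ± 0.04, CTSF at 0.37 ± 0.07 and CTSD at 0.30 ± 0.03. Of 26 basal and mesenchymal markers, 17 rose and none fell (median 0.16, adjusted p = 1.87e-07). SERPINE1, an inhibitor of plasminogen activators, was at 0.57 ± 0.04, FN1 (fibronectin) at 0.67 ± 0.06 and CD44 at 0.19 ± 0.03. Of 27 ERK output genes, 15 rose and none fell (median 0.10, adjusted p = 1.29e-05). SPRY4 was at 0.51 ± 0.05, DUSP6 at 0.35 ± 0.04 and DUSP4 at 0.35 ± 0.04. Of 23 YAP-TEAD targets, 14 rose and 4 fell (median 0.17, adjusted p = 0.000506; adjusted p = 0.128 with an estimated correlation). CCN2 was at 0.42 ± 0.04. Interferon genes (3 higher, 7 lower of 36, adjusted p = 0.751), chaperones (3 higher, 7 lower of 19, adjusted p = 0.345), NF-kappaB targets (7 higher of 18, adjusted p = 0.0889), stress genes (2 higher, 4 lower of 19, adjusted p = 0.544) and histones (5 lower of 24, adjusted p = 0.0842) did not pass, although STAT2 rose by 0.70 ± 0.06. Luminal markers (3 higher, 6 lower of 24, adjusted p = 0.165), estrogen receptor targets (10 higher, 4 lower of 32, adjusted p = 0.214), hypoxia genes (6 higher, 6 lower of 20, adjusted p = 0.544), antigen presentation (1 higher of 10, adjusted p = 0.751), immune markers (none called of 5, adjusted p = 0.989) and fibroblast, endothelial, adipocyte and erythroid markers (1 higher of 10, adjusted p = 0.701) did not pass either.

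In all, 15 of 30 lists passed in MDA-MB-231, and 9 with an estimated correlation. Adjusted over the list alone, counts rose for lysosome genes (27 higher), receptor kinases (15 higher), YAP-TEAD targets (16 higher), glycolysis genes (5 higher) and PI3K components (9 higher). They rose likewise for replication (29 lower), mitosis (33 lower), ribosomal proteins (72 lower), fatty acid genes (11 lower), ATF4 targets (18 lower), oxidative phosphorylation (1 higher, 25 lower) and basal markers (1 lower), and among lists that did not pass most for CDK inhibitors (10 higher, 7 lower). For cholesterol, hypoxia, apoptosis, estrogen receptor, interferon, CDK inhibitor and immune lists, the median, mean and test differed in sign. Across 11894 genes, which are not independent replicates, the response in MDA-MB-231 had a rank correlation of 0.30 with transcript length against 0.04 in MCF-7, and with length and GC offsets each of the 15 lists stayed past the threshold in its direction. Against a minimum change of 1.5-fold, 28 genes were higher and 1 lower in MDA-MB-231.

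**Figure D3:**
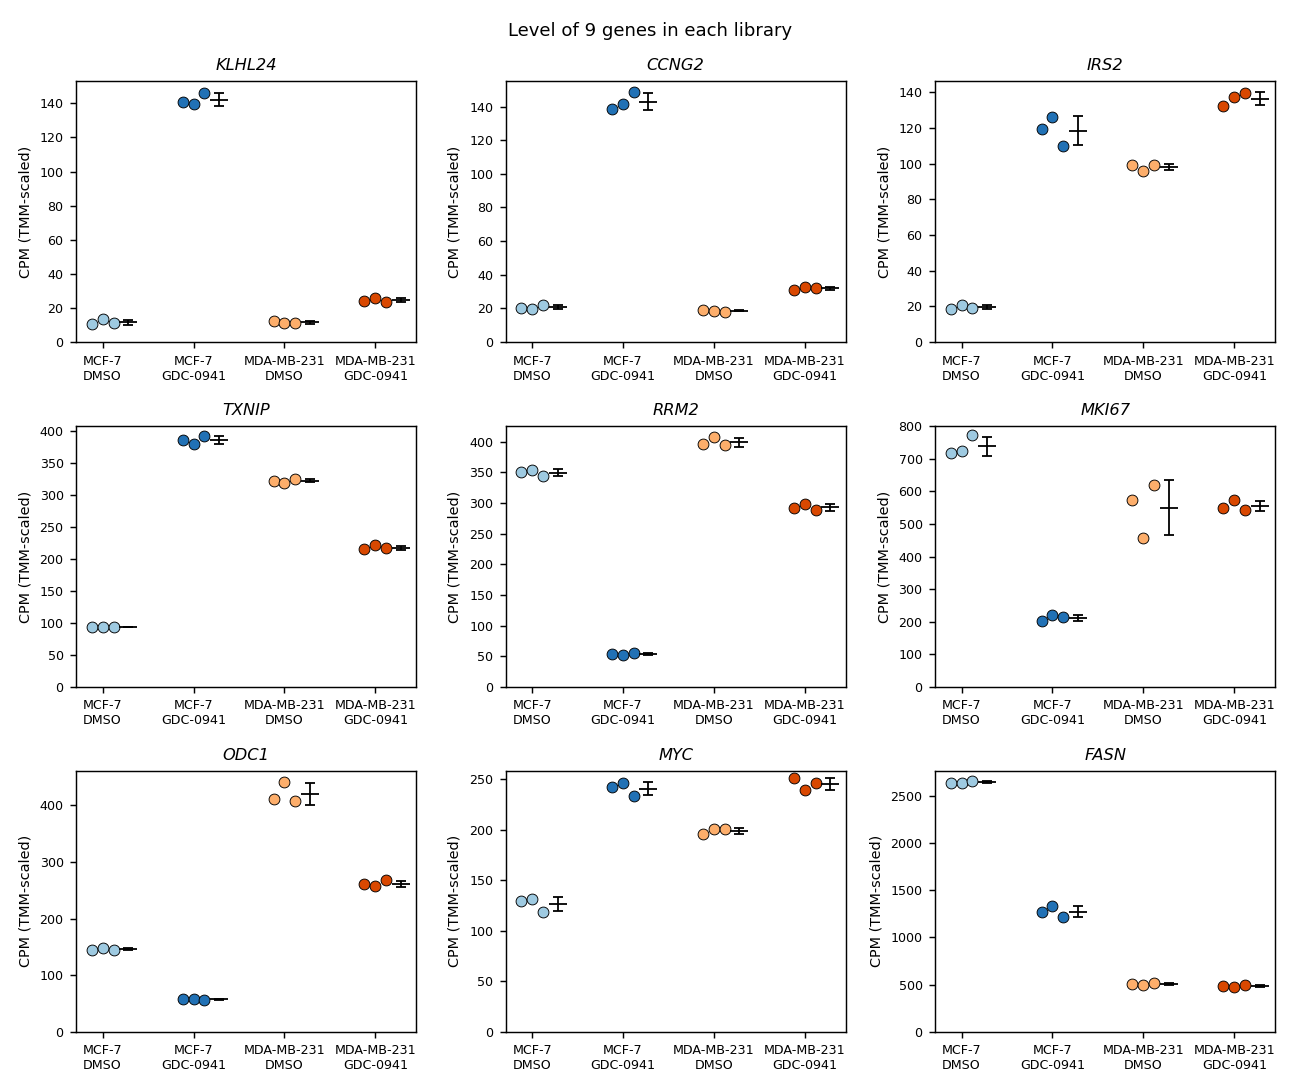
Level of 9 genes in each library, in TMM-scaled CPM on axes that start at 0, for the 4 groups. Points are libraries and bars are the mean ± SD of 3; TXNIP was higher after GDC-0941 in MCF-7 and lower in MDA-MB-231, and MKI67 fell in MCF-7.

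The third comparison set the responses of the lines against each other. Replication, mitosis and ribosome biogenesis genes fell less in MDA-MB-231 than in MCF-7, and FOXO targets rose less. Interferon genes, which rose in MCF-7 and did not pass in MDA-MB-231, differed between the responses, and a group of genes moved in opposite directions. MCM10 fell to 5.54 ± 0.393 CPM in MCF-7 and to 61.4 ± 0.874 CPM in MDA-MB-231 from similar DMSO levels of 77.7 ± 1.04 and 74.4 ± 0.738 CPM (difference 3.53 ± 0.09, adjusted p = 8.66e-28). The response differed for 8555 genes, of which 4808 were higher and 3747 lower in MDA-MB-231 relative to MCF-7. The higher calls, 56.2% of these, were 46.2% with upper quartile scaling and 49.4% with library size scaling.

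Genes called in the same direction in both lines outnumbered independent lists: 1774 were higher in both where 951.9 would be (odds ratio 4.16, Fisher's exact p = 2.14e-258), and 2055 were lower in both where 872.2 would be (odds ratio 9.30, exact p written by the software as 0). Opposite calls were fewer than independence gives. There were 385 higher in MCF-7 and lower in MDA-MB-231 where 901.3 would be, and 458 the other way where 921.2 would be. Genes are not independent replicates and both lines shared an estimate of the spread, so the Fisher's exact p-values are likely too small. Among 12229 genes with at least 1 CPM in both lines, the log2 fold changes had Pearson's r of 0.455 and Spearman's rho of 0.506 across genes, which are not independent replicates. Their SD was 0.807 in MCF-7 and 0.297 in MDA-MB-231. Over all 18028 genes tested, 4672 were called in both lines, and 3829 of these (82.0%) moved the same way. In 3364 of those that moved the same way (87.9%), the change was larger in MCF-7.

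The genes named by the fixed rule for the difference lay near 0 counts in 1 line in 8 of 10 cases, so counts over 3 libraries are given instead of fitted folds. Toward MDA-MB-231, CNNM1 (adjusted p = 0.000969) had 1722 and 2206 counts in MCF-7 DMSO and GDC-0941 and 0 and 16 in MDA-MB-231, and PCSK9 (adjusted p = 0.0056) had 8 and 0 against 767 and 861. KDR, the VEGF receptor (adjusted p = 2.43e-11), had 142 and 7 against 741 and 977. PCDH17 (adjusted p = 0.0248) had 740 and 361 against 0 and 4, and its call was lost without MDA-MB-231 DMSO replicate 1 (0.0501) or GDC-0941 replicate 3 (0.208). PDGFRB (adjusted p = 0.0219) had 5 and 0 against 518 and 780, lost without MCF-7 GDC-0941 replicate 1 (0.0551) or 2 (0.0571). Toward MCF-7, KCNK5 (adjusted p = 6.4e-05) had 594 and 1542 against 12 and 0, CYBRD1, a ferric reductase (adjusted p = 2.54e-17), 3 and 318 against 8940 and 13707, and HMGA2 (adjusted p = 8.38e-06) 0 and 25 against 7179 and 9945. CCN3 (adjusted p = 6.3e-09) had 1 and 58 against 1141 and 1120, and SLC1A2, a glutamate transporter (adjusted p = 0.000111), 455 and 2056 against 10 and 1. On GRCh38 with GENCODE 29, CNNM1 lies on chromosome 10, 99329099 to 99394330, PCSK9 on chromosome 1, 55039548 to 55064852, KDR on chromosome 4, 55078259 to 55125595, PCDH17 on chromosome 13, 57631810 to 57729311 and PDGFRB on chromosome 5, 150113837 to 150155872. KCNK5 lies on chromosome 6, 39188973 to 39229450, CYBRD1 on chromosome 2, 171522247 to 171558133, HMGA2 on chromosome 12, 65824131 to 65966295, CCN3 on chromosome 8, 119416306 to 119424353 and SLC1A2 on chromosome 11, 35251205 to 35420063.

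Chosen after their values were seen, several genes with reads in both lines moved in opposite directions. SOCS2 went from 15.9 ± 0.599 to 64.3 ± 0.395 CPM in MCF-7 and from 41.3 ± 1.8 to 24.4 ± 0.373 CPM in MDA-MB-231 (difference -2.77 ± 0.09, adjusted p = 1.5e-24). CD24, a surface glycoprotein, was at 0.68 ± 0.04 in MCF-7 and -0.74 ± 0.10 in MDA-MB-231, and DDIT4, an inhibitor of mTORC1 signalling, at 0.68 ± 0.06 and -0.65 ± 0.07. FN1 was at -0.84 ± 0.07 and 0.67 ± 0.06, and HSPG2 (perlecan) at -0.66 ± 0.08 and 0.84 ± 0.07. TXNIP, an anchor gene, differed by -2.61 ± 0.05 (adjusted p = 2.01e-30).

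Of 30 lists, 21 differed between the responses and 12 did with an estimated correlation. Replication genes differed by a median of 1.78 (37 genes toward MDA-MB-231, 2 toward MCF-7; adjusted p = 2.22e-67), mitosis genes by 0.73 (33 and 1; adjusted p = 2.05e-20), ribosome biogenesis genes by 0.74 (32 and 2; adjusted p = 2e-15) and FOXO targets by -1.14 (1 and 33; adjusted p = 2.53e-26). Interferon genes differed by -0.95 (2 and 25; adjusted p = 5.8e-07), chaperones by 0.65 (16 and 2; adjusted p = 5.59e-07), glycolysis genes by 0.42 (16 and 2; adjusted p = 2.41e-08), fatty acid genes by 0.58 (12 and 0; adjusted p = 7.69e-05) and cholesterol genes by 0.49 (19 and 1; adjusted p = 8.91e-05). CDK inhibitors differed by -0.57 (2 and 17; adjusted p = 7.96e-06), lysosome genes by -0.29 (7 and 24; adjusted p = 0.000129) and basal and mesenchymal markers by -0.57 (4 and 11; adjusted p = 0.0129). Ribosomal protein genes differed by -0.70 (1 and 69; adjusted p = 4.33e-30; adjusted p = 0.118 with an estimated correlation), and their share of counts moved in opposite directions as given above. Mitochondrially encoded mRNAs differed by -1.11 (0 and 13; adjusted p = 1.63e-16; adjusted p = 0.0596 with an estimated correlation), beside the mitochondrial shares given above.

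The other lists that differed at the preset correlation were receptor kinases (adjusted p = 0.00175; adjusted p = 0.118 with an estimated correlation), histones (adjusted p = 0.00199; adjusted p = 0.0596 with an estimated correlation), stress genes (adjusted p = 0.00138; adjusted p = 0.0793 with an estimated correlation) and NF-kappaB targets (adjusted p = 0.00645; adjusted p = 0.105 with an estimated correlation). YAP-TEAD targets (adjusted p = 0.0269; adjusted p = 0.262 with an estimated correlation), oxidative phosphorylation genes (adjusted p = 0.022; adjusted p = 0.502 with an estimated correlation, 0.0851 with upper quartile scaling and 0.0569 with library size scaling) and estrogen receptor targets (adjusted p = 0.019; adjusted p = 0.105 with an estimated correlation and 0.052 without MCF-7 GDC-0941 replicate 3) did so as well. The median of the estrogen receptor list, 0.08, turned to -0.03 with upper quartile scaling. Adjusted over the list alone, the counts toward MDA-MB-231 and MCF-7 were 38 and 2 for replication, 3 and 20 for CDK inhibitors, 2 and 27 for interferon, 2 and 70 for ribosomal proteins and 4 and 13 for basal markers.

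**Figure D4:**
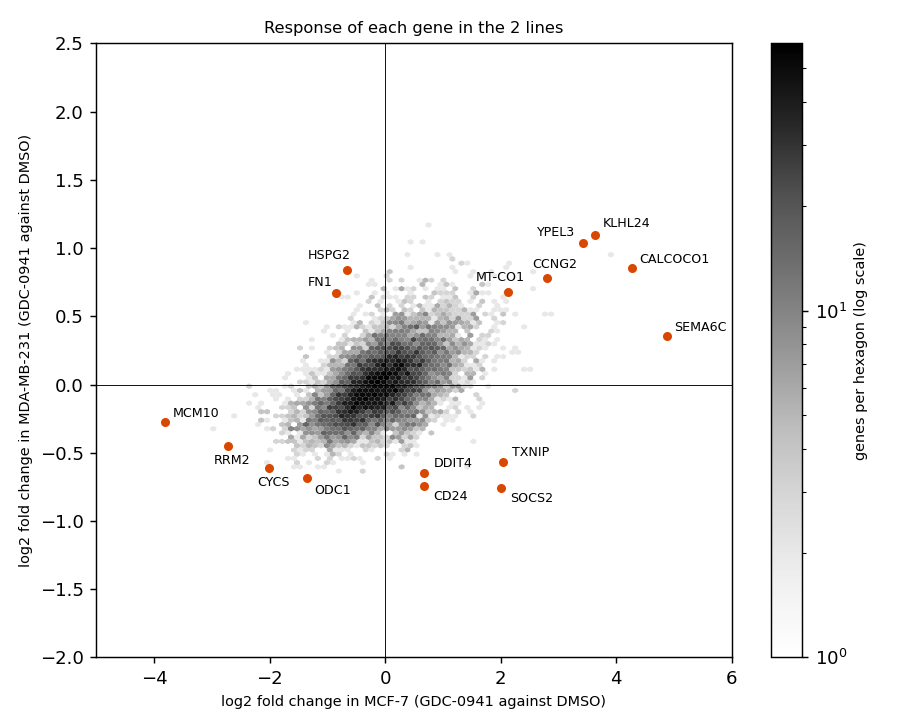
Log2 fold change of each of 12225 genes in MCF-7 (horizontal axis) against MDA-MB-231 (vertical axis), for genes with at least 1 CPM in both lines, as counts of genes per hexagon on a log scale; 4 further genes lie outside the axes. The 16 orange points are named genes: KLHL24 and CCNG2 rose in both lines and RRM2 fell in both, while SOCS2 and TXNIP rose in MCF-7 and fell in MDA-MB-231.

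The fourth comparison described how the DMSO-treated lines differ, which also checks the labels. MDA-MB-231 held mRNA of mesenchymal genes and MCF-7 held mRNA of luminal epithelial genes. ESR1, the estrogen receptor, was at 492 ± 13.1 CPM in MCF-7 and 0.127 ± 0.165 CPM in MDA-MB-231, and VIM (vimentin) at 0.432 ± 0.0795 and 975 ± 73 CPM. Of 18028 genes, 7347 were higher and 7450 lower in MDA-MB-231, with 49.65% of the calls higher, against 50.6% with RLE scaling and with DESeq2, 50.2% without mitochondrial genes and 53.5% with library size scaling.

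Ratios below are of counts over 3 libraries scaled to TMM library sizes, with counting intervals at 95% of the lower count. Against the floor of 3 counts over the group, KIRREL1 was at least 6057-fold higher in MDA-MB-231, G0S2 at least 4409-fold, SLC43A3 at least 4009-fold and CAVIN3 at least 3950-fold. FLNC, filamin C, had 4 counts in MCF-7 and 95942 in MDA-MB-231. RET, the receptor of glial neurotrophic factors, was at least 6794-fold lower in MDA-MB-231, LAD1 at least 4312-fold, ADCY1 at least 3610-fold, RAB25 at least 3021-fold and KCTD15 at least 2463-fold. On GRCh38 with GENCODE 29, KIRREL1 lies on chromosome 1, 157993273 to 158100262, G0S2 on chromosome 1, 209675420 to 209676388, SLC43A3 on chromosome 11, 57406954 to 57427580, CAVIN3 on chromosome 11, 6318946 to 6320647 and FLNC on chromosome 7, 128830377 to 128859274. RET lies on chromosome 10, 43077027 to 43130351, LAD1 on chromosome 1, 201373244 to 201399915, ADCY1 on chromosome 7, 45574140 to 45723116, RAB25 on chromosome 1, 156061160 to 156070514 and KCTD15 on chromosome 19, 33795933 to 33815763.

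Of the luminal genes, CDH1 (E-cadherin) was 6090-fold higher in MCF-7 (3693 to 10880), FOXA1 538-fold (443 to 660.0), GATA3 157-fold (147 to 169), EPCAM 19.5-fold (18.6 to 20.5), KRT8 17.3-fold (17.1 to 17.4) and KRT18 10.2-fold (10.1 to 10.3); KRT8 and KRT18 overlap on opposite strands. ESR1 was 3927-fold higher (2195 to 7867), and PGR, with 3 counts in MDA-MB-231, 1575-fold (539 to 7637). Of the line identity genes higher in MDA-MB-231, AXL was 14140-fold higher (8096 to 27370), VIM 2323-fold (1678 to 3317), ZEB1 421-fold (263 to 723), EGFR 99.6-fold (91.0 to 109) and CD44 27.1-fold (26.0 to 28.3). ERBB2 was 1.38-fold higher in MCF-7 (1.35 to 1.40); ERBB2 and ZEB1 overlap genes on the opposite strand.

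All 24 luminal markers were lower in MDA-MB-231 (median -7.90, adjusted p = 3.71e-72), as were 30 of 32 estrogen receptor targets (median -4.62, adjusted p = 2.53e-44), with 1 higher. Basal and mesenchymal markers were higher in 24 and lower in 1 of 26 cases (median 7.33, adjusted p = 4.89e-54), YAP-TEAD targets in 21 and 1 of 23 (median 2.09, adjusted p = 1.41e-30) and ERK output genes in 22 and 3 of 27 (median 3.02, adjusted p = 4.06e-21). Interferon genes were higher in 27 and lower in 8 of 36 (median 2.31, adjusted p = 1.38e-07), and all 10 antigen presentation genes were higher (median 5.47, adjusted p = 1.15e-06). Cholesterol genes (20 lower, 4 higher of 26, adjusted p = 3.13e-05) and ATF4 targets (22 lower, 9 higher of 33, adjusted p = 0.000398) were lower. Mitosis genes (29 higher, 4 lower of 36, adjusted p = 0.00439; adjusted p = 0.108 with an estimated correlation), NF-kappaB targets (17 higher, 1 lower of 18, adjusted p = 0.000507; adjusted p = 0.101 with an estimated correlation) and mitochondrially encoded mRNAs (13 higher of 13, adjusted p = 1.17e-05; adjusted p = 0.35 with an estimated correlation) were higher, the last beside a mitochondrial share of 0.785% in MCF-7 and 2.32% in MDA-MB-231. The other 18 lists did not pass; 9 of the 12 that did held with an estimated correlation. Each line stands for itself here, since 1 line of each kind was measured.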

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

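The tests of ribosomal protein genes against length and GC offsets and against scaling, the offsets themselves, the length slopes without each library, the comparison of histones with mitochondrial mRNAs, and the lists of heat shock factor targets and of translation factors with a 5' TOP motif were chosen only after the result was seen.

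The results below are those for which the response to GDC-0941 differed between the lines, by the interaction term of edgeR's quasi-likelihood fit at an adjusted p under 0.05 for a gene, or by camera at the preset correlation for a list. Values are log2 differences, MDA-MB-231 minus MCF-7, so that a positive value means a higher response in MDA-MB-231. Genes named only for the baseline are not included. In all, 135 differences are given, and 11 genes named for a treatment response had none past the threshold. With an estimated correlation, 9 of the 21 differences of fixed lists were lost, with the adjusted p given beside each in the report.

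Median differences were -0.39 for receptor tyrosine kinases, -1.14 for FOXO targets, 0.49 for cholesterol genes, 0.58 for fatty acid genes, 0.42 for glycolysis, 1.78 for G1/S and replication, 0.73 for mitosis, -0.57 for CDK inhibitors and p53 targets and 0.74 for ribosome biogenesis. They were -0.70 for ribosomal proteins, 0.65 for endoplasmic reticulum chaperones, -0.29 for lysosome genes, 0.0804 for estrogen receptor targets, -0.95 for interferon genes, -0.64 for NF-kappaB targets, -0.57 for basal and mesenchymal markers, -0.29 for YAP-TEAD targets and -0.52 for histones. They were -1.11 for mitochondrially encoded mRNAs, 0.20 for nuclear genes of oxidative phosphorylation, -0.77 for stress genes, -0.56 for translation factors with a 5' TOP motif and 0.81 for heat shock factor targets. The mean of the receptor kinase list was -0.01.

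Among FOXO targets and signalling genes the differences were -2.39 for YPEL3, -2.61 for TXNIP, -2.54 for KLHL24, -2.02 for CCNG2, -2.13 for IRS2, -1.33 for ERBB3, -0.95 for IRS1, -0.86 for INSR, -0.39 for IGF1R, -2.96 for PIK3IP1, -2.27 for DEPTOR, 0.75 for AKT1 and -0.65 for PTEN. Among cell cycle and cell death genes they were 2.26 for RRM2, 2.59 for UHRF1, 3.53 for MCM10, 2.56 for CDC6, 1.248 for FOXM1, 1.02 for BIRC5, 0.57 for CDC20, 0.72 for PLK1, 1.81 for MKI67, 0.53 for CCND1, -0.70 for CDKN1B, -1.90 for BBC3, -1.33 for TP53INP1 and -1.80 for BMF. Among ribosome and mitochondrial genes they were 1.30 for NOLC1, 0.99 for DDX21, 1.15 for SRM, 0.67 for ODC1, -0.65 for NPM1, -0.63 for MYC, -0.84 for RPL12, 0.38 for RPS26, -1.45 for MT-CO1, -0.57 for MT-ND3 and 1.41 for CYCS. Among metabolic genes they were 1.46 for LDHA, 1.31 for PKM, 0.45 for HK2, 1.01 for DHCR24, 0.46 for LDLR, 0.99 for FASN, 0.66 for SCD, 0.20 for SREBF1, 1.52 for SLC7A5, 0.50 for ASNS and 1.47 for SLC7A11, and among chaperone and lysosome genes 0.92 for HSPA5, -2.41 for CTSF, -2.70 for GABARAPL1, -0.34 for ULK1, 0.92 for CTSD and -0.21 for SQSTM1.

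Among immune, stress and histone genes the differences were -0.57 for STAT2, -1.05 for PARP14, 1.02 for OAS3, -2.55 for TNFAIP3, -0.96 for NFKBIA, -3.06 for FOS, -1.20 for KLF6, -1.89 for H2BC21 and -1.76 for H2AC6. Among lineage and ERK genes they were -2.59 for CAV1, -1.59 for CD44, -1.09 for CCN2, 1.81 for SPRY4, 0.43 for DUSP4, -0.51 for GATA3, -0.80 for CLDN3 and -0.38 for KRT18. Among heat shock and translation factors they were 1.36 for HSPH1, 1.03 for FKBP4, 1.28 for HSP90AA1, -1.92 for EIF4A2, -1.35 for EIF4B and -0.78 for EEF1A1, and among genes that moved in opposite directions -2.77 for SOCS2, -1.42 for CD24, -1.33 for DDIT4, 1.51 for FN1 and 1.49 for HSPG2. Among the largest changes in a line they were -4.41 for N4BP2L1, -4.53 for SEMA6C, -3.88 for YPEL1, -3.42 for CALCOCO1, -3.89 for FAXDC2, 3.31 for DPF1, 3.34 for FAM111B, 2.34 for CHAC2, -1.34 for TCP11L2, -0.41 for BAIAP3, -1.01 for PLA2G6, -1.44 for SNED1, 1.61 for ITGA10, -1.15 for AHNAK2, -0.56 for ARRDC4 and 1.04 for GAL. For genes near 0 counts in a line or group, the adjusted p of the difference was 0.0482 for PGR, 1.41e-09 for ADHFE1, 5.48e-08 for P2RY6, 0.000969 for CNNM1, 0.0056 for PCSK9, 2.43e-11 for KDR, 0.0248 for PCDH17, 0.0219 for PDGFRB, 6.4e-05 for KCNK5, 2.54e-17 for CYBRD1, 8.38e-06 for HMGA2, 6.3e-09 for CCN3 and 0.000111 for SLC1A2.

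The response in MDA-MB-231 rose with transcript length, with a rank correlation of 0.30 across 11894 genes, which are not independent replicates, against 0.04 in MCF-7. Without ribosomal protein and mitochondrial genes the correlation was 0.304, which argues against these short mRNAs as the whole source. The slope of log2 CPM on log2 length was 0.364, 0.289 and 0.375 in the DMSO libraries and 0.412, 0.441 and 0.402 in the GDC-0941 libraries, and the gap between the closest slopes of the groups was 0.312 of the widest range within a group. The ratio was 0.686 without MDA-MB-231 DMSO replicate 2 and 0.5001 without MDA-MB-231 DMSO replicate 3. At these ratios, length bias that varies from library to library cannot be told apart from a response to GDC-0941 that depends on transcript length, which stays open, as untested.

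The mitochondrial share of counts was higher after GDC-0941 in both lines. In MCF-7 the log2 fold changes of the 13 mitochondrial mRNAs ran from 0.80 to 2.13 with an SD of 0.448, above their largest standard error of 0.0964, which argues against a uniform loss of nuclear-encoded mRNA as the whole cause. Weaker poly(A) selection predicts that RNAs without a poly(A) tail rise too, and their median over that of mitochondrial mRNAs was -0.380 in MCF-7, but the 4 such RNAs measured had an SD of 0.79. Replication-dependent histone mRNAs, most of which also lack the tail, were higher in 12 and lower in 5 of 24 cases in MCF-7. In MDA-MB-231, where mitochondrial mRNAs rose too, histone mRNAs were higher in 0 and lower in 5. Histone mRNAs also follow DNA replication, and replication genes fell in both lines (median -1.90 in MCF-7 and -0.18 in MDA-MB-231). This link could hide a rise in MDA-MB-231, and whether it bears on the higher histone mRNAs in MCF-7 was not tested. Weaker selection still cannot be told apart from the treatment. A response of mitochondrial transcripts to GDC-0941 stays open, as untested.

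Ribosomal protein mRNAs rose in MCF-7 and fell in MDA-MB-231 at the preset correlation, but with an estimated correlation neither list call held (adjusted p = 0.382 and 0.143), nor did that of the difference (adjusted p = 0.118). After length and GC offsets their median in MDA-MB-231 was -0.22. The offsets rest on the longest transcript of each gene and may correct too little where a shorter one is expressed. Length or GC bias is therefore not excluded as the cause. The number of sign changes of the median under other scalings, 0, decides nothing. Those scalings moved the median of all genes by at most 0.12 in MCF-7 and by -0.02 to 0.02 in MDA-MB-231. That is less than the list's medians of 0.41 and -0.30. Across 78 genes with a processed pseudogene, the number of pseudogenes had a rank correlation of 0.0328 with the MCF-7 change and -0.151 with the MDA-MB-231 change. This argues against shared reads as the whole cause. Only genes with a pseudogene were counted, so ribosomal protein genes without one could not be compared. A response of these mRNAs that depends on the line stays open.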

How the results depend on the processing

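The tests with length and GC offsets, without mitochondrial genes, with library size alone and of calls at 1 CPM or more were chosen only after the result was seen.

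Of the counts of genes and lists under alternatives, 306 stayed within 1.5 times the value reported and 10 moved further. Against a 1.5-fold change, 2556 genes were higher and 2133 lower in MCF-7 and 28 and 1 in MDA-MB-231, and against a 2-fold change 3662 were higher and 3711 lower in MDA-MB-231 at baseline, since these tests ask for more. Lists called with an estimated correlation were 10 in MCF-7, 9 in MDA-MB-231 and 12 for the difference. Some lists that lost the call in MCF-7 had estimates far above the preset 0.01, such as 0.738 for ribosomal proteins. ATF4 targets (0.00204) and basal and mesenchymal markers (-0.0152) lost it there with estimates below the preset. A higher correlation cannot be the cause for ATF4 targets or basal markers, and no other cause was tested. The fry test, which compares no list with other genes, called 27 at baseline. Among named genes, 5176 values stayed on their side of the threshold, with direction compared only where a fit made a call. Another 131 lost the call, 86 of them in the test against a 1.5-fold change, 15 gained one and 4 reversed. Among values of the 70 list calls, 1355 kept direction and side and 41 lost the call, 30 of them with an estimated correlation. This tally of lists leaves out calls gained by other lists.

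In MDA-MB-231, AKT1 went from 0.01 to -0.22, IRS1 from 0.15 to -0.00957 and MKI67 from 0.01 to -0.18 with length and GC offsets, and MKI67 to -0.11 without MDA-MB-231 DMSO replicate 2, the library that differed most from its group; the cause was not tested. Upper quartile scaling moved the median of all genes by 0.12 in MCF-7 and -0.10 in the difference, and library size alone moved the baseline by 0.10. Without mitochondrial genes 43.0% of the MDA-MB-231 calls were higher, against 51.4%.

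Leaving out each library in turn gave 5499 to 6076 genes higher and 5109 to 5890 lower in MCF-7, 2365 to 2837 and 2403 to 3208 in MDA-MB-231, 4062 to 4907 and 3518 to 4034 for the difference, and 7275 to 7518 and 7141 to 7587 at baseline. Genes higher in both lines numbered 1491 to 1679, and lower in both 1832 to 2275. With all libraries, the 2916 genes higher in MDA-MB-231 and the 1774 higher in both lines lay above these ranges. Lists called numbered 21 to 22, 15 to 16, 20 to 21 and 12 to 13.

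With the replicate number as a block, 3 calls of lists and named genes were lost: basal and mesenchymal markers in MCF-7 (adjusted p = 0.0724), estrogen receptor targets in the difference (0.0608) and PIK3CA in MDA-MB-231 (0.0504). Same-numbered libraries had correlations of deviations of -0.00108, 0.0023 and 0.0202 in MCF-7 and -0.06, -0.16 and -0.07 in MDA-MB-231, so the numbers did not pair them, and not every library correlated best with its own number.

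The 10 splits of 6 libraries are too few for a share under 0.05. The real split called 11580 genes in MCF-7 and the highest other 0, 5677 in MDA-MB-231 and the highest other 1, and 14797 at baseline and the highest other 0; 1 split, the real one, gave as many. In edgeR's test, other splits with 0 genes held 303 to 386 genes at an unadjusted p under 0.05 in MCF-7, 440 to 1098 in MDA-MB-231 and 113 to 207 at baseline. For the difference, 1 of 100 drawn of 200 splits, the real one, gave 8555 genes, a share under 0.05. The highest other gave 8405. This share does not exclude chance for a difference between the lines, since the count followed the MCF-7 labels across the splits. The 8 that kept the MCF-7 labels gave 7434 to 8405, while the 6 that exchanged MCF-7 labels alone and the 85 that exchanged labels in both lines gave 0 (226 to 1410 at an unadjusted p under 0.05), a structure of the samples: the count follows the MCF-7 labels, so that the splits hardly test the difference between the lines. None of those drawn exchanged all labels of a line. Genes near the floor limit what depth can show: 900 MCF-7 and 214 MDA-MB-231 calls lay under 1 CPM.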

Other observations

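The lists of heat shock factor targets, of translation factors with a 5' TOP motif and of RNAs without a poly(A) tail, and the test of the TOP hypothesis, were chosen only after the result was seen.

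Heat shock factor targets, which encode chaperones of the cytosol and nucleus, fell in both lines. Of 17 measured, 15 fell and 1 rose in MCF-7 (median -1.18, camera adjusted p over 3 lists = 3.86e-17, 0.001 with an estimated correlation), and 15 fell and 0 rose in MDA-MB-231 (median -0.28, adjusted p = 2.01e-15, 0.0019 with an estimated correlation). Adjusted over the list alone, the counts were the same. The list shares 5 genes with the stress list (BAG3, DNAJB1, HSPA8, HSPB1 and HSPH1) and 1, FKBP4, with estrogen receptor targets; of the other 11, 10 fell and 0 rose in each line. HSPH1 was at -1.65 ± 0.04 in MCF-7 and -0.29 ± 0.04 in MDA-MB-231, HSP90AA1 at -1.67 ± 0.03 and -0.39 ± 0.03, and FKBP4, a co-chaperone of steroid receptors, at -1.30 ± 0.03 and -0.27 ± 0.04. The responses differed by a median of 0.81 (15 genes toward MDA-MB-231 and 1 toward MCF-7, adjusted p = 3.86e-16, 0.00127 with an estimated correlation).

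Translation factors with a 5' TOP motif, other than ribosomal proteins, rose in 19 and fell in 3 of 25 cases in MCF-7 (4 fell adjusted over the list alone; median 0.39, adjusted p = 2.26e-06, 0.0729 with an estimated correlation). In MDA-MB-231, 18 fell and 0 rose (median -0.23, adjusted p = 2.64e-13, 0.0113 with an estimated correlation). EIF4A2, which overlaps a gene on the opposite strand, was at 1.68 ± 0.04 and -0.24 ± 0.04, EIF4B at 1.33 ± 0.03 and -0.03 ± 0.03 (adjusted p = 0.565), and EEF1A1, which has close copies, at 0.56 ± 0.03 and -0.23 ± 0.03. RNAs without a poly(A) tail did not pass in MCF-7 (0 higher and 1 lower of 4, adjusted p = 0.665) or MDA-MB-231 (0 called of 4, adjusted p = 0.275).

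As a hypothesis, the ribosomal protein responses, whose difference between lines did not pass with an estimated correlation (adjusted p = 0.118), may be part of a response shared by mRNAs with a 5' TOP motif. It predicts that TOP mRNAs other than ribosomal proteins rise in MCF-7, and camera with an estimated correlation gave p = 0.0486 for them, which adjusted over the 3 lists was 0.0729 and did not pass. In MDA-MB-231 these mRNAs fell (adjusted p = 0.0113 with an estimated correlation), while the fall of ribosomal protein mRNAs did not pass with an estimated correlation (adjusted p = 0.143). The responses of the TOP mRNAs differed by a median of -0.56 (adjusted p = 0.00573 with an estimated correlation). The list was made and tested on the same data, so this stays a hypothesis.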
